A study of Mus musculus with 15 samples.

How the data were processed

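Crosslinking and immunoprecipitation with single-nucleotide resolution (iCLIP-seq) was carried out on Flag-tagged proteins in mouse cells. In N2A, a mouse neuroblastoma line, tagged Rnps1 (3 libraries), tagged Srsf11 (3 libraries) and tagged GFP (6 libraries) were induced with doxycycline for 48 hours from a Flp-in site. In neurons differentiated from embryonic stem cells, tagged Srrm4 (2 libraries) and tagged EGFP (1 library), here called GFP, were induced for 48 hours with 2 µg/ml doxycycline, starting 8 days after plating. Per the labels, cells received 0.15 J/cm2 of ultraviolet light at 254 nm, lysates were trimmed with RNase I, complexes were recovered with 10 µg of anti-Flag antibody, and complementary DNA was made with primers that carry a 4-base library barcode between random bases. Ultraviolet light at this wavelength crosslinks uridine more readily than other bases, so base composition is part of the background of every motif.

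The authors deposited 2 tables, one per cell type, whose values are the fraction of each of 4096 6-mers in each library. With values given to 8 decimals, each library sums to 1, or to 0.999999 in GFP replicates 2 and 3 of N2A, and no 6-mer is listed at 0. Demultiplexing with bcl2fastq, trimming with Trimmomatic, alignment with TopHat and the mm9 (NCBIM37) build are named per the submitters' processing notes, without versions or order. How duplicate reads were handled, which part of a read or of its surroundings was cut into 6-mers, and how many reads entered are not given in the sources used here. The depth of every library is therefore unknown, no interval for counting error is given, and the spread between libraries is the only error available. No genomic position belongs to a 6-mer value. The GFP column of the neuron table carries the name that the labels give to GFP replicate 1 of N2A, while the labels name the neuron GFP library differently and place it in this table. The column was therefore taken as the neuron GFP group, without a replicate number, and every neuron result rests on that reading. Its values equal those of GFP replicate 1 in N2A for 1 of 4096 6-mers (r = 0.839 over log2 values). The labels speak of 3 independent replicates without saying what separates them, so p-values measure the spread between these libraries, which may be partly technical.

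Values are printed as parts of the 6-mer total in ppm. Tests used log2(fraction + pseudocount), with a pseudocount of 0.01 times the median of the table, which is 2.05 ppm in N2A and 2.26 ppm in neurons. A log2 difference is on this scale, which slightly understates the change of rare 6-mers. Each 6-mer was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) with Benjamini-Hochberg adjustment over all 4096 6-mers at 0.05. The 12 N2A libraries shared 1 fit with 3 groups. In neurons the single GFP library was assumed to vary like the Srrm4 libraries, and each Srrm4 library was also set against GFP on its own. Figures and counts were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

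The tests, the 21 motif lists, 18 fixed 6-mers and the rule for naming 6-mers were chosen before the data were examined. The rule takes, per comparison, the 10 largest increases and the 5 largest decreases among called 6-mers for which every library of one group lies beyond every library of the other, the fixed 6-mers whatever their result, and members of lists that pass the list test. With nothing called in neurons, it takes those of largest mean log2 ratio at least 1.5-fold from GFP in both Srrm4 libraries. Lists hold the 6-mers with TGC, TGC in CTG or TGC repeats, purines only, GAR repeats (R is A or G), pyrimidines only, TCTC or CTCT, 5 or more T, 5 or more A, TG repeats, the Rbfox, Nova and Pumilio motifs, G runs, polyadenylation signals, AU-rich elements, 5' splice sites, 3' splice sites, branch points and CG. A further pair is technical: 6-mers with the barcode of any library and 6-mers with at least 5 bases of the sequencing adapter. Lists overlap, and overlapping 6-mers are not independent.

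A list's value in a library is the mean log2 value of its members minus the mean over all 6-mers. Lists were compared by a two-sided exact permutation test with Benjamini-Hochberg adjustment over all lists and N2A comparisons. The smallest p is 0.0119 for 3 against 6 libraries and 0.1 for 3 against 3. Camera of limma was run beside it with a preset correlation of 0.01 and with an estimated correlation, adjusted over all lists and comparisons. No list call of camera held with the estimated correlation in any comparison.

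Once the values were seen, the 6 GFP libraries of N2A fell into 2 sets of 3. GFP replicates 1 to 3 lay near Rnps1 and GFP replicates 4 to 6 near Srsf11. The labels do not name such sets, and which set goes with which protein was read from the values themselves, which favours small differences within a set. Of the 20 ways to give 3 GFP libraries to each protein, 6 repeat no reverse transcription primer within a set, and the division seen is one of them. Values of 6-mers within the sets come from a limma fit with 4 groups (library set as a block). Replicate numbers were checked as pairs: deviations of Rnps1 and GFP libraries of the same number, from their group means, correlated over 6-mers with r of 0.295, 0.367 and 0.269, all over 0.1. The numbers were therefore taken as pairs, as read from the values and not from the labels. From the means within the set the r were 0.613, 0.490 and 0.463, and each library correlated best with its own number. From the group means, GFP replicate 3 and Rnps1 replicate 2 also correlated, with r of 0.238. With 3 libraries per group such a match can arise by chance.

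The fits were tested on simulated data, with 200 of 4096 6-mers changed and 20 draws per comparison. The simulated noise was independent between 6-mers and between libraries and held no library sets. The shares below, and the runs of the list test, therefore do not cover the set structure of the real GFP libraries. For neurons the shares also assume that the single GFP library varies like the Srrm4 libraries, which cannot be checked. In the real neuron fit GGTTCG was not called at a log2 difference of -1.43. High neuron shares therefore do not make an absence of calls there a sign of no change. With simulated spreads taken from each 6-mer's shrunken variance, 65.7% of 1.5-fold, 91.9% of 2-fold and 98.8% of 3-fold changes were recovered for Rnps1 against GFP, and 4.19% of calls were false. The recovered shares were 66.6%, 91.3% and 98.8% for Srsf11 against GFP (4.69% of calls false) and 53.7%, 87.2% and 97.6% for Rnps1 against Srsf11 (4.97% false). For Srrm4 against GFP they were 99.6%, 100% and 100%, but 12.1% of calls were false. With spreads drawn from the fitted prior, recovery for Srrm4 against GFP was 84.0%, 96.7% and 98.5%, with 5.91% of calls false. With that second noise model the N2A comparisons recovered 63.2%, 63.4% and 50.1% of 1.5-fold changes, in the same order, with 4.50%, 5.09% and 4.48% of calls false. The list test gave a p under 0.05 in 3 of 50 simulated runs without a shift of the GAR list and in 50 of 50 runs with a log2 shift of 1.

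Alternatives were 2 other pseudocounts, leaving out the rarest 6-mers, median centring, rescaling to 1 total, quantile normalization, values relative to each library's base composition, eBayes with trend and robust options, leaving out 6-mers with a barcode or adapter or of low complexity, fits of only the groups compared, the replicate number as a block, the primer as a random block, library weights, and each library left out in turn. The library sets, the fits within 1 set, the set block for values relative to base composition and the removal of 6-mers with CG were added after the values were seen.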

Results

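The RNA under 3 splicing factors was compared with the background of tagged GFP. Rnps1 is an RNA-binding protein of the exon junction complex and Srsf11 an SR-related protein. Srrm4, also called nSR100, is a neuronal SR-related protein that promotes inclusion of microexons, the very short exons of neuronal transcripts. The study asked how such exons are recognised, and the motifs under these proteins bear on that question. N2A mouse neuroblastoma cells gave 3 Rnps1, 3 Srsf11 and 6 GFP libraries. Neurons derived from embryonic stem cells gave 2 Srrm4 libraries and 1 GFP library, which has no replicate and was assigned by its table, since its column has the name of an N2A library. Each library is described by the share of 4096 6-mers in its reads, from 5.56 to 6723 ppm of the 6-mer total, and the depth behind these shares is unknown. Sequences are written as DNA, so T stands for U in the RNA.

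Rnps1 libraries were rich in A and Srsf11 libraries rich in T, and GFP libraries were of both kinds. T made up 22.1% ± 0.153 (SD, n = 3) of 6-mer positions with Rnps1 and 30.7% ± 0.639 (SD, n = 3) with Srsf11. It made up 22.9% ± 0.328 (SD, n = 3) in GFP replicates 1 to 3 and 29.9% ± 0.261 (SD, n = 3) in GFP replicates 4 to 6. A held 31.1% ± 0.225 with Rnps1, 24.3% ± 0.401 with Srsf11, 29.5% ± 1.72 in GFP replicates 1 to 3 and 24.1% ± 0.313 in GFP replicates 4 to 6 (SD, n = 3 each). Against all 6 GFP libraries, T differed by -4.31 percentage points with Rnps1 and by 4.29 with Srsf11, and by -0.821 and 0.800 within the library sets. The first 2 differences had exact two-sided permutation p of 0.0238 and 0.0357, both 0.143 after Benjamini-Hochberg adjustment over 12 tests of base shares. None of the 12 passed that adjustment. In neurons T held 29.5% ± 0.469 (SD, n = 2) with Srrm4 and 28.4% with GFP.

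**Figure D1:**
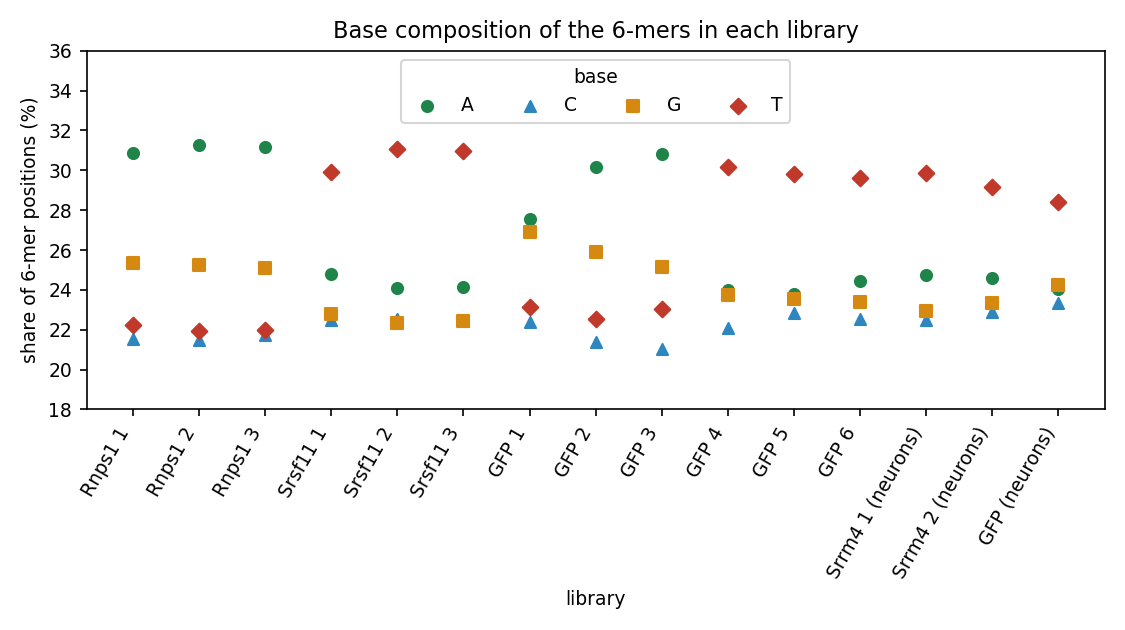
Share of 6-mer positions held by each base (y axis, percent) in each of the 15 libraries (x axis), with 1 point per base and library. GFP replicates 1 to 3 have 22.9% T on average, near the 22.1% of Rnps1, and GFP replicates 4 to 6 have 29.9%, near the 30.7% of Srsf11.

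The division of the GFP libraries was visible over all 6-mers. Log2 values correlated over 6-mers with r from 0.875 to 0.960 between Rnps1 and GFP replicates 1 to 3, and from 0.801 to 0.877 between Rnps1 and GFP replicates 4 to 6. Srsf11 correlated from 0.949 to 0.984 with GFP replicates 4 to 6 and from 0.803 to 0.865 with GFP replicates 1 to 3. The GFP sets correlated with each other from 0.843 to 0.874. Between the GFP sets, replicates 1 to 3 minus 4 to 6, the purine list differed by 1.04 on the log2 scale, the GAR list by 1.02, the list of T tracts by -1.19 and the pyrimidine list by -0.94. Because Rnps1 lies with one set and Srsf11 with the other, values within the set are also given. They come from GFP replicates 1 to 3 for Rnps1 and from GFP replicates 4 to 6 for Srsf11, a division made after the values were seen.

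Against GFP, 20 of 31 GAR-repeat 6-mers were higher in Rnps1 libraries, 13 of 19 T-tract and 15 of 40 G-run 6-mers were lower, and 6-mers with CG went both ways (305 higher, 158 lower). GAAGAA, a classic exonic splicing enhancer sequence, rose from 1826 ± 1086 (SD, n = 6) ppm with GFP to 3581 ± 29.5 (SD, n = 3), a log2 difference of 1.21 (SE 0.43). AGAAAG rose from 1307 ± 887 to 2841 ± 122 ppm, by 1.43 (SE 0.50). GGTTCG fell from 228 ± 102 to 68.7 ± 1.43 ppm, a log2 difference of -1.60 (SE 0.27), and GGGGGG from 2987 ± 2007 to 901 ± 49.8, of -1.48 (SE 0.42). The adjusted p from limma with Benjamini-Hochberg adjustment were 0.0498, 0.0443, 0.00328 and 0.0209 in this order. Within the library set the log2 differences of these 6-mers were 0.39, 0.48, -1.61 and -2.10, so that the increases were smaller and GGGGGG differed more. The calls of GAAGAA and AGAAAG each ended in 6 of the 9 omissions of a library, those of any Rnps1 replicate and of GFP replicates 4, 5 or 6. That of GAAGAA also ended with a pseudocount of 0.1 times the median, without the rarest 6-mers and with median centring. Both ended with quantile normalization, with trend and robust options, with only Rnps1 and GFP in the fit, and with only Rnps1 and GFP replicates 1 to 3.

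In all, limma called 1372 of 4096 6-mers, 909 higher and 463 lower with Rnps1. This balance turned with library weights (1440 higher, 1638 lower) and against GFP replicates 4 to 6 alone (1354 higher, 1565 lower). The other increases named by the rule were AGGAAG (1.19), ACGAAG (1.18), CGAAGA (1.16), AGCCGA (1.13), GAAGGA (1.13), AAGGAA (1.11), ACGACG (1.03) and GGAAGG (1.02), with values within the set of 0.39, 0.45, 0.47, 0.55, 0.38, 0.35, 0.57 and 0.36. The other decreases were CGCGTG (-1.43), CGCGGT (-1.43) and CGCGCG (-1.35), with -1.64, -1.06 and -1.47 within the set. Among the fixed 6-mers, GGAGGA rose by 0.90 (0.40 within the set) and GGTAAG, a 5' splice site sequence, by 0.29 (0.30). TTTTTT fell by 1.12 on the log2 scale, TGTGTG, a binding site of CELF proteins and TDP-43, by 1.12, and TATTTA, the AU-rich element, by 0.91. Their values within the set were -0.69, -0.82 and -0.53. All 20 named 6-mers that were called were also called within the library set, in the same direction. Not called were TCTCTC (-1.22, adjusted p = 0.0878 from limma), AATAAA (-0.52), TTCATT (-0.51), CTTCTT (-0.48), TGCATG (-0.39), TGTAAA (-0.34), CTAACT (-0.21), TTGCAG (0.17), TGCTGC (0.12), AAAAAA (0.11) and TTCTGC (0.08). Within the set TCTCTC stood at -0.24, TTCATT at -0.0403, TGCATG at -0.0738, TGTAAA at -0.14, CTAACT at -0.00186 and CTTCTT at 0.0876, the last of opposite sign, none called. Within the set limma called TGCTGC at 0.43, TTCTGC at 0.35, TTGCAG at 0.34, AATAAA at -0.90 and AAAAAA at -0.62, the last with the opposite sign to its pooled value. The fit with the replicate block called the same 5 at the same values.

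By list, GAR repeats, the enhancer class bound by SR and Tra2 proteins, had 20 of 31 members higher, 0 lower and 11 not called, and 26 higher when adjusted over the list alone. The list difference was 0.76, and 0.25 within the library set, where 22 members were called higher. Of the 64 purine 6-mers, 24 were higher, 2 lower and 38 not called, with 38 higher and 3 lower adjusted over the list alone. The purine list held 8.85% ± 0.126 (SD, n = 3) of the 6-mer total with Rnps1, 8.03% ± 0.736 (SD, n = 3) in GFP replicates 1 to 3 and 3.52% ± 0.152 (SD, n = 3) in GFP replicates 4 to 6. Its list difference was 0.63, and 0.10 within the set (31 higher, 5 lower). Of the 19 6-mers with a T tract, 13 were lower (19 adjusted over the list alone), with a list difference of -0.99 and of -0.40 within the set (16 lower). AU-rich elements had 7 of 8 members lower (8 adjusted over the list alone; -0.49, and -0.38 within the set with 8 lower). G runs, which hnRNP H and F bind, had 15 of 40 lower and 1 higher (18 and 2 adjusted over the list alone; -0.43, and -0.59 within the set with 23 lower and 1 higher). TG repeats had 3 of 14 lower (2 adjusted over the list alone; -0.52, and -0.21 within the set with 5 lower).

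TGC, the core of the motif reported for Srrm4, had 32 of 255 6-mers higher and 17 lower with Rnps1 (22 and 14 adjusted over the list alone), with a list difference of -0.02, and 0.11 within the set with 121 higher and 18 lower. TGC in repeats had 15 of 54 members higher and 0 lower (13 adjusted over the list alone; 0.16), and 42 higher within the set (0.28). The 3' splice site list had 7 of 16 members higher and 1 lower (7 and 1 adjusted over the list alone; 0.14, and 0.20 within the set with 11 higher and 1 lower), and the Nova list 47 of 192 higher and 4 lower (44 and 2 adjusted over the list alone; 0.08, and 0.12 within the set with 97 higher and 8 lower). Pyrimidine 6-mers (2 of 64 lower, 0 adjusted over the list alone) had a list difference of -0.43, and 0.04 within the set, where 16 were higher and 4 lower. TCTC 6-mers had 4 of 80 higher and 5 lower (2 and 3 adjusted over the list alone; -0.23, and 0.01 within the set with 30 higher and 6 lower). A tracts had 0 of 19 called (0.47, and -0.07 within the set with 2 higher and 6 lower). The remaining values were -0.06 for the Rbfox motif (0 of 8 called), -0.38 for polyadenylation signals (0 of 2), -0.35 for the Pumilio motif (1 of 4 lower, 2 adjusted over the list alone) and -0.15 for branch points (6 of 32 higher, 7 lower, the same adjusted over the list alone). Within the set these were 0.00 (0 called), -0.56 (1 lower), -0.17 (1 lower) and -0.08 (10 higher, 8 lower). For the list with CG, 305 of 1185 members were higher and 158 lower (313 and 168 adjusted over the list alone), its list difference was -0.01 and its median change 0.04, of opposite sign, and within the set the difference was -0.05 (423 higher, 236 lower). The 5' splice site list likewise had a difference of -0.04 and a median change of 0.04, with 1 of 16 higher and 2 lower (the same adjusted over the list alone), and of -0.08 within the set (3 higher, 2 lower). The technical lists moved with the group too. Barcode 6-mers had 80 of 363 lower and 39 higher (-0.22, and -0.18 within the set with 102 lower and 57 higher). Adapter 6-mers had 47 of 126 higher and 8 lower (0.17, and 0.13 within the set with 63 higher and 9 lower). GAAGAA, AGGAAG, CGAAGA and GGAAGG hold 5 bases of the adapter and are themselves adapter 6-mers. The adapter rise thus shares members with the purine and GAR rises. Leaving out adapter 6-mers removes these members and does not test them. GGTTCG holds GGTT, the barcode of GFP replicates 3 and 4, but was highest in GFP replicate 1 (415 ppm).

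No list passed the exact two-sided permutation test with Rnps1 after adjustment. By exact permutation the GAR list had p = 0.0238 and the barcode, adapter and AU-rich lists p = 0.0119, the smallest possible, and each had an adjusted p = 0.125. Camera of limma called 14 of 21 lists with the preset correlation and 0 with the estimated correlation, where the adjusted p was 0.686 for GAR repeats, 0.732 for purines, 0.684 for T tracts and 0.428 for G runs and AU-rich elements. With the replicate number as a block, which pairs Rnps1 with GFP replicates 1 to 3, limma called 2065 6-mers (1405 higher, 660 lower), and within the library set 2061 (1411 and 650). Of the 909 higher and 463 lower calls, 834 and 404 were also made within the set in the same direction and 0 in the opposite one. The count was 761 without Rnps1 replicate 1, 467 without replicate 2 and 434 without replicate 3. Of the 20 named calls, 12, 13 and 15 ended without Rnps1 replicates 1, 2 and 3, and 8, 7 and 8 without GFP replicates 4, 5 and 6. CGCGTG, CGCGGT, CGCGCG, GGTTCG and TGTGTG were called in all 9 omissions.

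**Figure D2:**
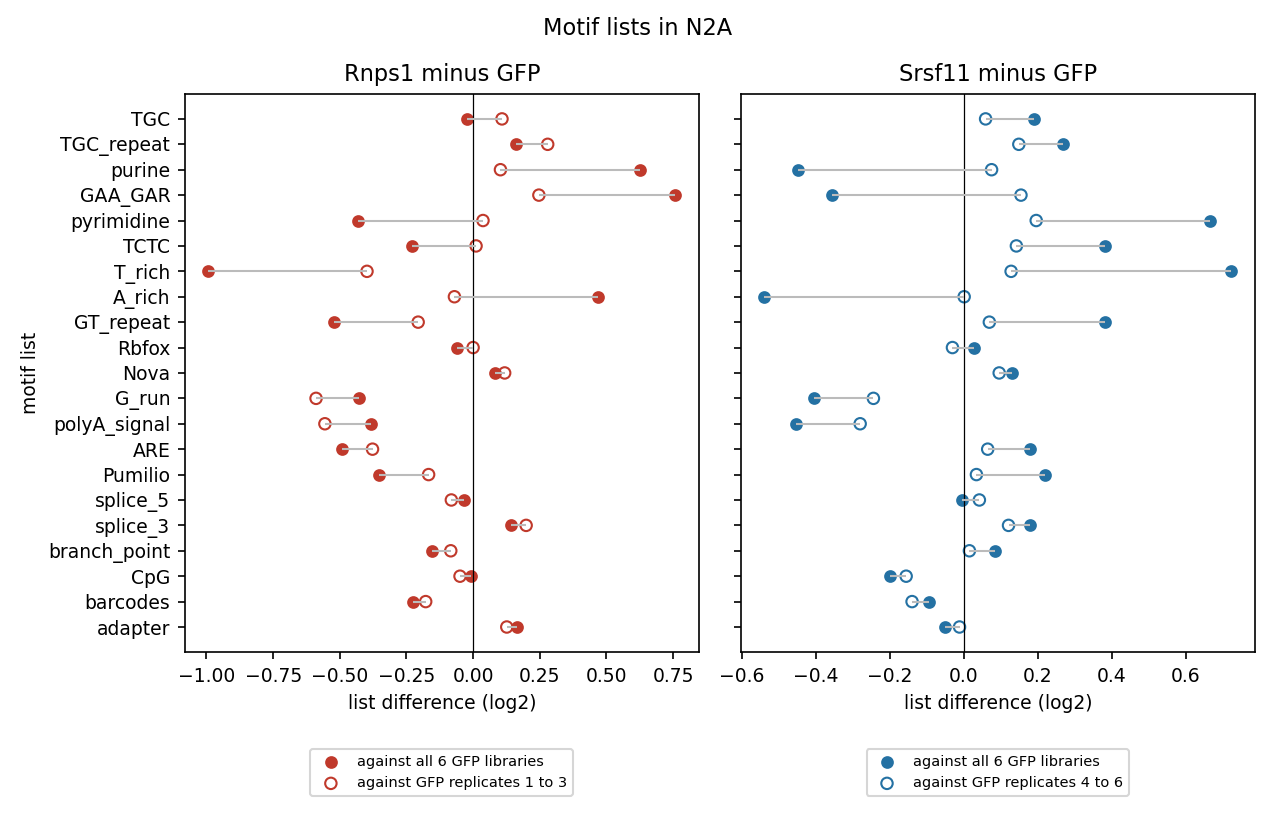
List difference (x axis, log2) of each motif list (y axis) for Rnps1 (left) and Srsf11 (right) against GFP in N2A; filled points use all 6 GFP libraries and open points the 3 GFP libraries of the same set. For purines the value is 0.63 against 0.10 with Rnps1 and -0.45 against 0.07 with Srsf11, while G runs lie below 0 in both panels under both choices.

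Of the 85 6-mers that limma called between Srsf11 and GFP, 78 were lower, and 62 of these hold CG, out of 1185 6-mers with CG. GGGTCG fell from 546 ± 341 (SD, n = 6) ppm with GFP to 106 ± 1.61 (SD, n = 3) with Srsf11, a log2 difference of -2.09 (SE 0.45). GGTCGG fell from 569 ± 309 to 118 ± 2.74 (-2.07, SE 0.38), CGCCGG from 1273 ± 770 to 276 ± 5.83 (-1.98, SE 0.41), GGGGGG from 2987 ± 2007 to 654 ± 58.1 (-1.94, SE 0.42) and CGGGCC from 695 ± 406 to 177 ± 7.15 (-1.76, SE 0.41). Their adjusted p from limma with Benjamini-Hochberg adjustment were 0.0421, 0.0351, 0.0364, 0.0429 and 0.0494. The increases were small: CTCTAC rose from 182 ± 24.2 to 255 ± 8.35 ppm (0.49, SE 0.11, adjusted p = 0.0429 from limma). Within the library set the decreases were -1.32, -1.46, -1.33, -1.32 and -1.07 and CTCTAC differed by 0.35. GGGTCG and GGTCGG hold GGTC, the barcode of GFP replicate 5, and CGCCGG holds CCGG, that of GFP replicate 1. No Srsf11 library carries these barcodes, and the alternative without barcode 6-mers removes all of these 6-mers. GGGTCG and GGTCGG were higher in GFP replicate 2 (1001 and 1003.5 ppm) than in GFP replicate 5 (276 and 386). CGCCGG had 2380 ppm in GFP replicate 1 and 2101 in GFP replicate 2.

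Limma called 7 6-mers higher and 78 lower with Srsf11, and 1334 had an unadjusted p under 0.05. This balance turned for values relative to base composition (587 higher, 235 lower) and without GFP replicate 6 (313 higher, 255 lower). The other 6 increases were TAGGCG (0.45), CGCTAT (0.41), CCGCTT (0.40), ATCCTC (0.39), CCTGCA (0.38) and TGACAT (0.33), with 0.38, 0.38, 0.33, 0.33, 0.29 and 0.28 within the set. All 12 named 6-mers that were called were also called within the set in the same direction. Of the fixed 6-mers only GGGGGG was called. TTCTGC, a UGC sequence in a pyrimidine context, differed by 0.57 (adjusted p = 0.0795 from limma), and by 0.30 within the set, where it was called (adjusted p = 0.0448). GGTAAG differed by 0.34 (0.32 within the set, called there) and AAAAAA by -1.43 (-0.71, called there). TCTCTC, a CU repeat of the kind PTB proteins bind, differed by 1.35 (adjusted p = 0.120 from limma; 0.37 within the set) and CTTCTT by 0.78 (0.21). TTCATT (0.60), TTTTTT (0.51), TATTTA (0.42), TTGCAG (0.40), TGCTGC (0.36), TGTAAA (0.24), TGTGTG (0.21), CTAACT (0.21), TGCATG (0.19), GGAGGA (-0.32), GAAGAA (-0.48) and AATAAA (-0.77) were not called. Within the set these were 0.13, 0.0796, 0.0334, 0.23, 0.0497, 0.0430, -0.0851, 0.00730, -0.13, 0.19, 0.34 and -0.38, none called. TGTGTG, TGCATG, GGAGGA and GAAGAA thus had the opposite sign there.

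Among the lists, CG had 62 of 1185 members lower and 3 higher with Srsf11, and 191 and 22 adjusted over the list alone. Its list difference was -0.20 with a median change of -0.09, and -0.16 within the library set, where 259 members were lower and 26 higher. G runs had 2 of 40 lower (15 adjusted over the list alone; -0.41, with a median change of -0.07, and -0.24 within the set with 9 lower). Pyrimidine 6-mers had a list difference of 0.67, with 0 of 64 called and 52 higher adjusted over the list alone, and 0.20 within the set (5 higher). TCTC 6-mers had 1 of 80 higher (46 higher and 1 lower adjusted over the list alone; 0.38, and 0.14 within the set with 13 higher and 1 lower). TGC in repeats had 1 of 54 higher (26 adjusted over the list alone; 0.27, and 0.15 within the set with 11 higher), and the 3' splice site list 1 of 16 lower (11 higher and 1 lower adjusted over the list alone; 0.18, and 0.12 within the set with 1 higher and 1 lower). All TGC 6-mers differed by 0.19 (1 of 255 higher, 2 lower; 0 and 1 adjusted over the list alone), and by 0.06 within the set (17 higher, 13 lower), and Nova 6-mers by 0.13 (0.10 within the set, 8 higher and 1 lower). T tracts differed by 0.72 with 0 of 19 called, and by 0.13 within the set (0 called). Purines differed by -0.45 and GAR repeats by -0.36, with 2 of 64 lower and 0 of 31 called, and by 0.07 and 0.15 within the set, of opposite sign, although 5 purine 6-mers were called lower there and 0 higher. Barcode 6-mers had 10 of 363 lower (-0.09, and -0.14 within the set with 48 lower and 1 higher) and adapter 6-mers 2 of 126 lower (-0.05, and -0.01 within the set with 11 lower). The Rbfox list had a difference of 0.03 and a median change of -0.02, of opposite sign, and -0.03 within the set.

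No list passed the exact two-sided permutation test with Srsf11 after adjustment. By exact permutation the CG, Nova and 3' splice site lists had p = 0.0119, the smallest possible, and an adjusted p = 0.125. Camera of limma called 14 of 21 lists with the preset correlation and 0 with the estimated correlation, where the adjusted p was 0.355 for CG and 0.684 for pyrimidines, TCTC, TGC repeats and G runs. Within the library set limma called 459 6-mers (114 higher, 345 lower), which include 77 of the 78 lower and all 7 higher calls. Without Srsf11 replicate 1, 2 or 3 limma called 0 6-mers, without GFP replicate 4 it called 6, and without GFP replicate 6 it called 568. The 12 named calls all ended in the first 4 of these omissions, and 7, 2 and 2 of them ended without GFP replicates 2, 3 and 5. Centring each library on its median gave 169 calls (45 higher, 124 lower) and quantile normalization 169 (59 higher, 110 lower), a larger share of higher calls than 7 of 85.

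Set against each other, Rnps1 libraries held more GA-rich purine 6-mers and Srsf11 libraries more pyrimidine and T-rich 6-mers, a difference that moved with the library set. GAAAGA had 2744 ± 94.8 (SD, n = 3) ppm with Rnps1 and 525 ± 32.0 (SD, n = 3) with Srsf11, a log2 difference of 2.38 (SE 0.63, adjusted p = 0.0170 from limma). TCTCTC had 587 ± 60.8 and 3591 ± 1099 ppm, a log2 difference of -2.57 (SE 0.60, adjusted p = 0.0141 from limma). Relative to the GFP libraries of the own set, these differences were 0.27 and -0.60, neither called. TGTGTG (-1.33) and TATTTA (-1.32) were lower with Rnps1 than with Srsf11 and were called within the sets too, at -0.73 and -0.56 (adjusted p = 0.0103 and 0.0184 from limma).

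Limma called 1722 6-mers between the proteins, 896 higher and 826 lower with Rnps1. This balance turned relative to base composition (379 higher, 435 lower), with the replicate block (1320 higher, 1371 lower) and without the rarest 6-mers (817 higher, 822 lower). With the library set as a block limma called 347 (243 higher, 104 lower). Of the calls without the set block, 75 higher and 84 lower were also made with it, and 0 in the opposite direction. The other increases named by the rule were AGAAAG (2.18), AAAGAA (2.11), AAGAAA (2.01), TCGCGG (1.81), AGGAAG (1.80), CGAAGA (1.77), AAGGAA (1.73), AGAAGA (1.71) and GAAGGA (1.69). Within the sets these were 0.28, 0.25, 0.21, -0.31, 0.20, 0.39, 0.22, 0.07 and 0.19, none called. The decreases were CTCTCT (-2.52), TTTCGT (-2.12), TTCGTT (-2.09) and TTGTTT (-2.02), with -0.66, -0.53, -0.36 and -0.48 within the sets, of which TTTCGT and TTGTTT were called. Of the fixed 6-mers GAAGAA (1.69), AAAAAA (1.54) and GGAGGA (1.22) rose, with 0.04, 0.09 and 0.21 within the sets. TTTTTT (-1.63), CTTCTT (-1.26), TTCATT (-1.12), TGTAAA (-0.58), TGCATG (-0.58) and CTAACT (-0.42) fell, with -0.77, -0.12, -0.17, -0.18, 0.05 and -0.01 within the sets, none called there. TTCTGC (-0.49, adjusted p = 0.0505 from limma), GGGGGG (0.46), AATAAA (0.25), TTGCAG (-0.24), TGCTGC (-0.23) and GGTAAG (-0.05) were not called. All but GGTAAG (-0.0248) had the opposite sign within the sets: TTCTGC 0.0485, GGGGGG -0.78, AATAAA -0.52, TTGCAG 0.10 and TGCTGC 0.38, of which only TGCTGC was called there (adjusted p = 0.0213 from limma). Of the 26 named 6-mers that were called, 4 were also called within the sets in the same direction, and TCGCGG and TGCATG had the opposite sign there.

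All 31 GAR 6-mers were higher with Rnps1 than with Srsf11 (31 adjusted over the list alone; list difference 1.12), and 1 was called within the sets (0.09). Purines had 52 of 64 higher (54 adjusted over the list alone; 1.07, and 0.03 within the sets with 0 called). Pyrimidines had 62 of 64 lower (64 adjusted over the list alone; -1.10, and -0.16 within the sets with 2 called), and T tracts 19 of 19 lower (19 adjusted over the list alone; -1.72, and -0.53 within the sets with 9 called). AU-rich elements had 7 of 8 lower (7 adjusted over the list alone; -0.67), with 4 lower within the sets (-0.44). CG 6-mers had 294 of 1185 higher and 44 lower (240 and 30 adjusted over the list alone; 0.19), with 146 higher and 8 lower within the sets (0.11). TGC 6-mers had 59 of 255 lower and 15 higher (42 and 10 adjusted over the list alone), with a list difference of -0.21, and 0.05 within the sets, of opposite sign (21 higher, 8 lower). Adapter 6-mers, among them GAAGAA, AGGAAG, CGAAGA and AGAAGA, had 50 of 126 higher and 18 lower (0.22, and 0.14 within the sets with 8 higher). Barcode 6-mers had 46 of 363 higher and 103 lower (-0.13, and -0.04 within the sets with 10 higher and 11 lower).

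With 3 against 3 libraries the exact two-sided permutation test cannot give a p under 0.1, and no list passed it; the lowest adjusted p was 0.147. Camera of limma called 13 of 21 lists with the preset correlation and 0 with the estimated correlation, where the adjusted p was 0.684 for purines, GAR repeats, pyrimidines and T tracts and 0.428 for AU-rich elements and CG. The count of called 6-mers was 992 without Rnps1 replicate 1 and 1052 without Srsf11 replicate 1. It was 2 without Rnps1 replicate 2, 2 without Rnps1 replicate 3, 2 without Srsf11 replicate 2 and 2 without Srsf11 replicate 3. These 4 omissions ended all 26 named calls, and omission of Rnps1 replicate 1 or Srsf11 replicate 1 ended 6 or 5.

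In neurons no 6-mer was called, and the 5 of lowest value by the naming rule all hold CG. GGTTCG had 109 ± 19.0 (SD, n = 2) ppm with Srrm4 and 294 with GFP, a log2 difference of -1.43 (SE 0.17). GCGTTA (-1.30), GTTCGA (-1.30), CGTTAT (-1.22) and TAGCGG (-1.19) came next. In both Srrm4 libraries 86 6-mers were at least 1.5-fold lower than GFP and 0 were at least 1.5-fold higher, with the same single GFP library in both ratios. The lower count depended on the library, with 319 in Srrm4 replicate 1 and 86 in replicate 2. No value here separates Srrm4 from that 1 library.

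Of the fixed 6-mers, 4 hold UGC, the sequence reported for Srrm4 upstream of microexons, and none was called: TGCTGC, TTCTGC, TTGCAG (0.22) and TGCATG (-0.11). TGCTGC had 477 ± 10.7 (SD, n = 2) ppm with Srrm4 and 495 with GFP, a log2 difference of -0.05 (SE 0.05), and TTCTGC had 404 ± 9.04 and 352, a difference of 0.20 (SE 0.05). The largest positive value among the fixed 6-mers was that of GGTAAG, the 5' splice site sequence, with 272 ± 4.49 against 203 ppm (0.41, SE 0.05). The other positive values were GAAGAA (0.27), TATTTA (0.19), TTCATT (0.19), CTTCTT (0.16), TCTCTC (0.14), TTTTTT (0.13), TGTAAA (0.11), GGAGGA (0.11) and AATAAA (0.07). The negative ones were GGGGGG (-0.51), AAAAAA (-0.25), CTAACT (-0.07) and TGTGTG (-0.03).

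By list, 0 of the 1185 CG 6-mers were called over all 6-mers and 371 were lower and 32 higher adjusted over the list alone, with a list difference of -0.23. Like all neuron counts this one rests on a single GFP library and can be a property of that library. G runs had 14 of 40 lower adjusted over the list alone (-0.15). The 3' splice site list had 7 of 16 higher adjusted over the list alone (0.16), and the 5' splice site list 2 higher and 1 lower of 16 (0.12). Pyrimidines (0.17), T tracts (0.24), AU-rich elements (0.19), GAR repeats (0.11), Nova (0.10), TGC in repeats (0.07), TCTC (0.07) and all TGC 6-mers (0.02) had 0 members called either way. So did A tracts (0.11), the Pumilio motif (0.10), TG repeats (0.08), purines (0.07), branch points (0.06) and the Rbfox motif (-0.05). Polyadenylation signals had a list difference of 0.02 and a median change of -0.01, of opposite sign. Barcode 6-mers had 12 of 136 lower and 1 higher adjusted over the list alone (-0.07). Adapter 6-mers had 6 of 126 lower adjusted over the list alone (list difference -0.06, median change 0.00).

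With the spread resting on 2 Srrm4 libraries, limma called 0 6-mers at a lowest adjusted p = 0.0972, while 1712 had an unadjusted p under 0.05, and limma with trend and robust options called 1207 (565 higher, 642 lower). Camera of limma called 10 of 21 lists with the preset correlation, CG among them, and 0 with the estimated correlation, where the adjusted p was 0.725 for CG, 0.684 for G runs, the 3' splice site list and Nova, and 0.760 for pyrimidines and T tracts. With 2 libraries against 1 there are too few splits for a permutation test to give a small p, and none was made.

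The changes with Rnps1 and with Srsf11 against the same 6 GFP libraries had a Pearson's r of 0.04 and a Spearman's rho of -0.10 over 4096 6-mers, which are not independent replicates. Within the sets these were 0.66 and 0.58. Unchanged groups simulated against these controls gave a mean r of 0.32, with 95% of 500 simulations between -0.82 and 0.96, and a mean covariance of 0.0128 against the observed 0.00617, so the pooled r says neither that the changes were alike nor that they were unrelated. With the GFP libraries split 3 and 3, r ran from -0.55 to 0.66 over the 20 divisions, with a median of 0.03, and the highest was the division into library sets. Within the sets the proteins have separate controls and shared 126 lower calls (54.7 for independent lists) and 94 higher calls (39.3).

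The Srrm4 change in neurons correlated more with that of Srsf11 than with that of Rnps1, except for values relative to base composition against all 6 GFP libraries. In that setting r was 0.57 with Srsf11 and 0.58 with Rnps1, and within the library sets it was 0.83 and 0.48. For values as given, over 6-mers the Srrm4 and Srsf11 log2 differences correlated with r = 0.57 (rho 0.50), and with r = 0.84 (rho 0.74) within the library set. The Srrm4 and Rnps1 differences correlated with r = 0.39 (rho 0.29), and with r = 0.43 (rho 0.30) within the set. The neuron and N2A tables have separate GFP libraries. Without 6-mers that contain CG the correlations were 0.41 with Srsf11 and 0.25 with Rnps1 against all 6 GFP libraries, and 0.79 and 0.32 within the sets.

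**Figure D3:**
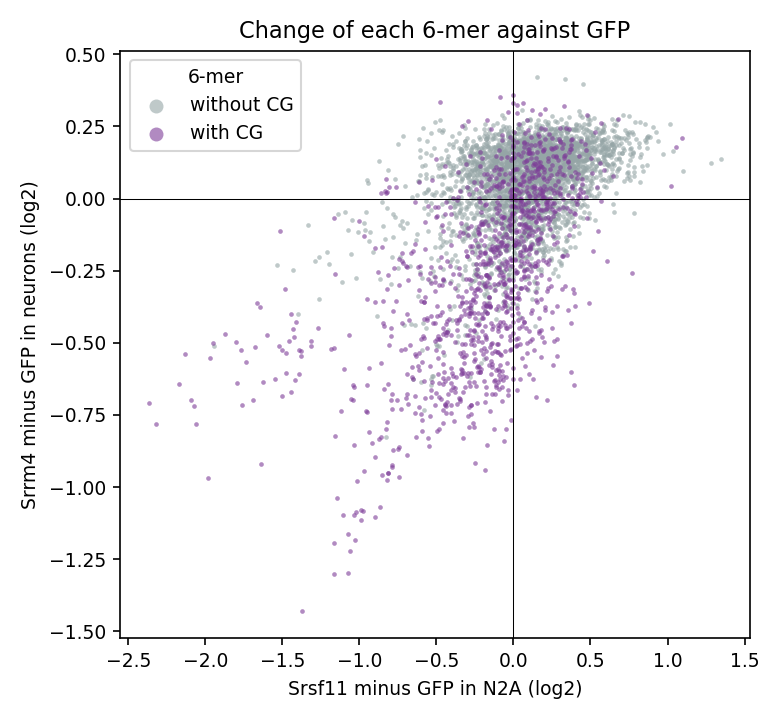
Log2 difference from GFP of each 6-mer, with Srsf11 against all 6 GFP libraries in N2A (x axis) and with Srrm4 in neurons (y axis); each point is one of 4096 6-mers, coloured by whether it contains CG. GGTTCG, a 6-mer with CG, has the lowest Srrm4 value at -1.43, and over all 6-mers r = 0.57.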

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

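The tests of tRNA were written before the 6-mers they use were looked at, but after GGTTCG and GTTCGA of the same tRNA arm were seen. The tests of library set, base composition, similarity and splits of the libraries were chosen after results were seen.

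GFP replicate 3 in N2A lay far from the other 5 GFP libraries in the 5' splice site list, with a value of 0.55 where the others ran from 0.33 to 0.41 (gap over range 0.670). It was the only 1 of 43 measures to do so, and chance alone gives about 1 in 20.

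With Rnps1 the purine list differed from GFP by 0.63 and the GAR list by 0.76. A difference between library sets could account for the purine list, which differed from GFP replicates 1 to 3 by 0.103 (SE 0.0560 over 3 pairs), although the pairs were all above 0 (0.213, 0.0308 and 0.0643). For GAR repeats the difference from GFP replicates 1 to 3 was 0.247 (SE 0.0580, pairs 0.356, 0.228 and 0.157). This argues against a set difference as the whole cause for GAR repeats, without excluding it. The exact permutation p within the set was 0.1, the smallest possible for 3 against 3 libraries. Relative to base composition, by a linear fit on base counts, the lists still differed within the set. The values were 0.0767 (SE 0.0260) for purines and 0.228 (SE 0.0296) for GAR repeats. The second argues against base composition as the whole cause for GAR repeats, while the first, over 3 pairs, excludes nothing. The sets were read from the values, which makes differences within them small, and a preference of Rnps1 for GAR repeats stays open.

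The CG list differed from GFP by -0.20 with Srsf11 (median change -0.09; 62 of 1185 lower, 3 higher) and by -0.23 with Srrm4 (0 called), with adjusted p = 0.355 and 0.725 from camera of limma with an estimated correlation, so no call stands behind the list as a whole. If the GFP libraries held more tRNA, 6-mers of the tRNA T arm would have a lower median than random lists of equal CG content and level: the median of 8 was -0.28 in N2A, at percentile 1.02 of 10000 lists, and -0.68 in neurons, at percentile 0. This fits tRNA reads as part of the pattern, with limits. T-arm 6-mers overlap each other and also GTTCGA, already seen to be low (-1.08 in N2A and -1.30 in neurons). TTCGAA and TTCGAT, for example, are GTTCGA shifted by 1 base. The random lists were not matched on such overlap, so the percentiles are not independent of what was seen. Limma called none of the 8, GAATCC was near 0 (-0.03 and -0.00240), and neurons have 1 GFP library. At equal base counts 6-mers with CG still differed in N2A, by -0.28 (SE 0.0398) with Srsf11 and by -0.23 (SE 0.0344) within its set. This argues against base counts as the whole cause in N2A, without excluding a part for them. With Srrm4 the -0.29 (-0.35 and -0.24 in its 2 libraries) has no spread for the single GFP library and excludes nothing, and binding of either protein away from CG-rich RNA stays open.

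The Srrm4 change in neurons resembled the Srsf11 change in N2A, with r = 0.57, and 0.84 within the set. It remained without CG 6-mers (r = 0.41) and for values relative to base composition, by a linear fit on base counts (r = 0.57). These values argue against CG 6-mers themselves, or base counts as fitted, as the whole cause, without excluding either. Other 6-mers of reads that hold CG stay in when CG 6-mers are left out. Reads rich in CG could therefore still be the source. CG 6-mers and base composition were removed separately and not together. A property of GFP libraries in general would make Srrm4 resemble Rnps1 as much: within the sets that r was lower, 0.43 (SD of the difference 0.0712), and 0.48 against 0.83 relative to base composition (SD 0.0526). Against all 6 GFP libraries, relative to base composition, it was as high, 0.58 against 0.57 (SD 0.0565), so this explanation stays open. These SDs combine the spread over omissions of single N2A libraries, with no neuron library left out. They are not standard errors and understate the uncertainty. A property of GFP replicates 4 to 6 and the neuron GFP library alone could also give the resemblance, as could RNA targets that Srsf11 and Srrm4 share.

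Every regrouping of the libraries was fitted as well. For Rnps1 against GFP, 2 of 84 splits gave as many calls as the real 1372, and the highest other, 2510, sets GFP replicates 4 to 6 against the rest. For Srsf11 against GFP, 4 of 84 gave as many as the real 85, the highest other being 2695 for GFP replicates 1 to 3 against the rest. These point to sample structure, namely the library sets, within which 2061 and 459 6-mers were called. Rnps1 against Srsf11 (real 1722, other 0, 1 of 10 splits), Rnps1 against GFP replicates 1 to 3 (1614, 0, 1 of 10) and Srsf11 against GFP replicates 4 to 6 (837, 0, 1 of 10) have too few splits.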

How the results depend on the processing

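Single 6-mer results were counted under the alternatives set beforehand, omissions apart. Of these, 1717 kept their direction and their state, called or not called. A further 109 lost the call, 152 gained it, 42 changed sign without a call in either fit and 4 reversed. Under omissions these were 759, 269, 26, 9 and 0, and under alternatives added later 186, 32, 77, 29 and 9. Omissions in neurons have no test and entered by direction alone, so the 759 overstates stability. The cause was not tested unless given. The unknown depth limits rare 6-mers most. Rescaling changed no count of called 6-mers, since every library already sums to 1 or 0.999999.

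For Rnps1 against GFP the count of 1372 became 802 with only the 2 groups fitted, 3078 with library weights (1440 higher, 1638 lower; their estimation ended with a convergence warning), 2061 with the library set as a block, 2919 against the other set's GFP libraries (1354 higher, 1565 lower), and 434 to 1792 over omissions. For Srsf11 against GFP the count of 85 became 169 with median centring (45 higher, 124 lower), 169 with quantile normalization (59 higher, 110 lower), 822 relative to base composition (587 higher, 235 lower), 0 with only 2 groups, 352 with the primer as a random block (126, 226), 933 with weights (361, 572), 459 with the set block (114, 345), 2688 against the other set (1641, 1047), 837 with only Srsf11 and GFP replicates 4 to 6 (238, 599), and 0 to 568 over omissions (313, 255 at 568). For Rnps1 against Srsf11 the count of 1722 became 814 relative to base composition (379, 435), 3424 with only 2 groups, 207 with the primer block, 3625 with weights, 347 with the set block, and 2 to 1052 over omissions. For Srrm4 the count of 0 became 1790 relative to base composition (997, 793) and 1207 with trend and robust options (565, 642). The counts of lists past the permutation test were 0 throughout, 0 to 0 over omissions, which shows no stability, since the smallest possible p leave little or no room for another count.

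The replicate block, which pairs libraries of the same number, gave 2065 calls for Rnps1 against GFP. It ended none of the 20 named calls. GCGTTA and CGTTAT, chosen after their values were seen, lost theirs (-0.75 and -0.73), and GTAAGT, GAAAGA and TTCCAG, chosen likewise, gained one (0.34, 0.45 and 0.39). Srsf11 with GFP and Rnps1 with Srsf11 share only a number (r of 0.247, -0.0517 and -0.479, and of -0.247, -0.0211 and -0.0813). Not every library correlated best with its own number. The block gave 2728 (1653 higher, 1075 lower) and 2691 (1320, 1371) calls for these comparisons. GFP libraries whose number no Srsf11 library shares add nothing to the blocked difference. Srsf11 was thus compared only with the GFP libraries of the other library set. The fit with only those GFP libraries gave 2688 calls (1641 higher, 1047 lower). The blocked count for Srsf11 therefore cannot separate an effect of blocking from the difference between library sets. In neurons no paired analysis was possible, because the GFP library there is single and its column carries no number of its own. Leaving out a Srrm4 library gives a value with no test.

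Relative to base composition, AAAAAA with Rnps1 against GFP reversed to -0.69, TTTTTT with Rnps1 against Srsf11 to 0.19 and AATAAA with Srrm4 to -0.21. AAAAAA was -0.62 with the replicate block, the set block, both, and only GFP replicates 1 to 3. These settings all compare Rnps1 with GFP replicates 1 to 3, so the equal value is fixed by the design. With the set block TCGCGG (-0.31), TGCTGC (0.38), TGCATG (0.0531) and TTCCAG (0.29) reversed for Rnps1 against Srsf11, and against the other set TGCTGC (-0.18) and TTCCAG (-0.17) for Rnps1 against GFP.

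The Rnps1 and Srsf11 similarity of 0.04 became 0.47 relative to base composition, 0.66 with the set block, 0.68 with both and -0.32 without CG 6-mers. For Srrm4 and Rnps1 the 0.39 became 0.58, 0.43, 0.48 and 0.25 in this order, and for Srrm4 and Srsf11 the 0.57 became 0.57, 0.84, 0.83 and 0.41. With the set block, base differences in percentage points became 0.26 for A and -0.0253 for C with Srsf11, -0.758 for G with Rnps1, and 0.0135 for C between them.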

Other observations

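The 6-mers of this paragraph and the next were chosen after their values were seen. CAGGTA, which spans an exon end and the 5' splice site, had 456 ppm with Rnps1 and 321 with GFP in N2A (0.52, 0.37 within the set; adjusted p = 0.00673 and 0.00359 from limma). With Srsf11 it differed by 0.15, and by 0.30 within the set, and with Srrm4 by 0.42 (293 against 218 ppm). GTAAGT, the inner part of the 5' splice site, differed by 0.13 with Rnps1 (0.34 within the set), 0.45 with Srsf11 (0.24) and 0.40 with Srrm4. GTGAGT, another form of that site, differed by 0.03 with Rnps1 (0.14 within the set), 0.22 with Srsf11 (0.12) and 0.16 with Srrm4, and the 5' splice site list by -0.04 with Rnps1 (-0.08). CTGCTG differed by 0.34 with Rnps1 (0.50 within the set), 0.44 with Srsf11 (0.28) and 0.13 with Srrm4.

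Within the library set, 6-mers with CG stood at both ends with either protein. With Rnps1 the 10 largest increases and 4 of the 5 largest decreases contain CG, and the CG list as a whole differed by -0.05 (423 higher, 236 lower). ACCGAC had 67.3 ± 5.32 (SD, n = 3) ppm with Rnps1 and 37.5 ± 2.89 (SD, n = 3) in GFP replicates 1 to 3, a log2 difference of 0.81 (SE 0.12, adjusted p = 8.0e-04 from limma), followed by CGTACC (0.73), CACCGA (0.73), CGCCAG (0.72) and GCGACT (0.70). The decreases were larger: GGGGCG (-1.65), GCGGGG (-1.65), CGCGTG (-1.64) and CTCGCG (-1.62). With Srsf11, GCGTTA (-1.45), AATGCG (-1.37) and GGTTCG (-1.36) were among the largest decreases within its set, and 8 of the 10 largest increases contain CG too, such as GGCGAA (0.41) and AGCGGA (0.40).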
